A study of Populus tremula x Populus alba with 72 samples.

How the data were processed

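Leaf RNA of hybrid poplar (Populus tremula x alba, one micropropagated clone) was sequenced in 72 libraries, 4 for each combination of leaf position (expanded or growing), air (charcoal-filtered, or with 80 or 100 ppb ozone) and day (2, 8 or 13). Per the labels' protocols, libraries were stranded and made from poly(A)-selected RNA, and read in pairs. The deposited values are a signal per gene and library: normalized counts, as the authors' table is named. Per the submitters' processing notes, TopHat2 2.12, featureCounts, Subread 1.6.1 and DESeq2 1.24.0 were used; the notes give neither the role nor the parameters of each, and the genome build is not given in the sources used here.

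The unit was tested on the values. In each column every value was a whole multiple of one step (100% within a tolerance of 0.01 reads, largest deviation 0.00061), so the deposited signal is a whole read count divided by one factor per library. Size factors recomputed by the median-of-ratios method from the recovered reads differed from the steps by at most 1.04e-09%. Recovered reads per library came to 23.2 M to 54.3 M (median 39.4 M), and the table lists 34699 genes; totals of the deposited values lay between 31.2 M and 48 M. All columns belong to a labelled sample and none was left out.

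Genes were tested when they had a value of at least 10 in at least 4 libraries, which left 27780. The tests used log2 of the deposited value with a pseudocount of 1, limma 3.58.1 in R 4.3.3 with a mean per group, all 72 libraries in one model (54 residual degrees of freedom) and eBayes with a trend. Adjusted p-values are Benjamini-Hochberg within each contrast, called at 0.05, two-sided, and no replicate block was used, since the labels do not say what a replicate number marks. The contrasts were ozone against the control of the same leaf position and day, growing against expanded leaves in controls, the difference of the ozone response between leaf positions, 100 against 80 ppb over the mean of the days, and the change of the response from day 2 to day 13. The tests, the alternatives and the rule for named genes were fixed before the data were examined. Contrasts at 100 ppb alone, by day or over time in controls, shared calls between days and scores of the response per library were added after the data were seen. Groups were set by the labels alone.

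Named genes are those with an adjusted p under 0.05, a mean of at least 100 normalized counts in the higher group and all treated replicates on one side of the other group's mean on the log2 scale (growing leaf replicates for the leaf position contrast; no such condition for the difference of responses). Since the deposited table pairs no identifier with a name, at most 2 that rose and 2 that fell are given per contrast, those with the largest change. For counts of 5 or fewer outside the rule, the largest in each direction are named. For the same reason 35 lists of genes by product description, fixed beforehand, could not be made, and the camera and fry tests planned on them were left out.

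Principal components were computed on the centred log2 values of the tested genes. Correlations of changes are Spearman's across genes, with jackknife standard errors over libraries. Shared calls are set beside the overlap of independent lists, and comparisons with shared controls beside simulated unchanged groups. Those simulations take a single spread per gene over all groups. Ratios printed for genes with 1 to 3 reads in a group carry 95% counting intervals, with a floor of 3 reads over the group at 0 reads. Scores of the response are the median log2 difference from the control mean over genes that rose at least 2-fold at 100 ppb in expanded leaves of another day (day 13, or day 8 for the day 13 expanded leaves themselves; growing leaves of day 13 are scored on expanded leaves of that day), compared by two-sided exact permutation tests of 4 against 4 libraries, which cannot go below p = 0.0286.

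Alternatives were pseudocounts of 8 and 0.25, no filter, a filter at 50, robust eBayes, TMM scaling, equal totals, a 2-fold threshold, models of the compared libraries alone, a replicate block, each library left out in turn (not counted in ranges of the share of higher genes), and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads; statmod 1.5.0 and data.table (version 1.17.8) were also used. The tests were tried on counts simulated for all libraries from a single mean and a single spread per gene over all groups, with their real depths (27190 genes). Changes were set at 100 ppb in expanded leaves on day 13, only in genes with a mean of at least 50. The recovery therefore does not cover genes with fewer reads. There limma recovered 73% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, with 10 calls among unchanged genes, edgeR 74% and 95% (9 calls), and DESeq2 77% and 96% (25 calls). The real groups differed in spread (median SD per gene from 0.148 to 0.308). The simulation leaves this out, so it does not show how many false calls the real data give.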

Results

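Messenger RNA was sequenced from leaves of young hybrid poplars of one clone kept in charcoal-filtered air, the same air with 80 ppb ozone or the same air with 100 ppb ozone in the daytime. Leaves of 2 positions, expanded and growing, were sampled after 2, 8 and 13 days, which gave 18 groups of 4 libraries. The 72 libraries held 23.2 M to 54.3 M reads assigned to genes (median 39.4 M; M stands for mega-reads), and 27838 to 29119 genes had reads in a given library. The 10 most abundant genes took 3.52% to 10.9% of a library. Of 34699 genes listed, 1923 had no read in any library and 27780 passed the expression filter and were tested. Log2 changes are given ± their standard error, and group means of normalised read counts ± SD with n = 4. The labels do not say which tree or chamber a replicate number stands for, so the p-values measure only the spread between these libraries. The deposited table does not pair gene identifiers with names or descriptions. Genes are therefore given by identifier alone, and whether they have near-identical copies that share reads was not assessed here.

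On the first principal component leaf position separated the libraries by more than ozone did on days 2 and 8, but not on day 13. On this component of the log2 values, which held 60.6% of the variance, control growing leaves moved from −212 ± 10.2 on day 2 to −96.1 ± 7.22 on day 8 and 27.9 ± 16.2 on day 13 (SD, n = 4). Control expanded leaves lay at −35.4 ± 19.9, 72.8 ± 15.2 and 103 ± 39.3 on those days. At 100 ppb on day 13 the means were 205 ± 7.8 in expanded and 120 ± 24.3 in growing leaves, both above their controls. The second component held 14.1% of the variance. The 4 expanded control libraries of day 13 were spread widely, with a median SD per gene of 0.308 on the log2 scale against 0.148 in the growing controls of day 8.

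**Figure D1:**
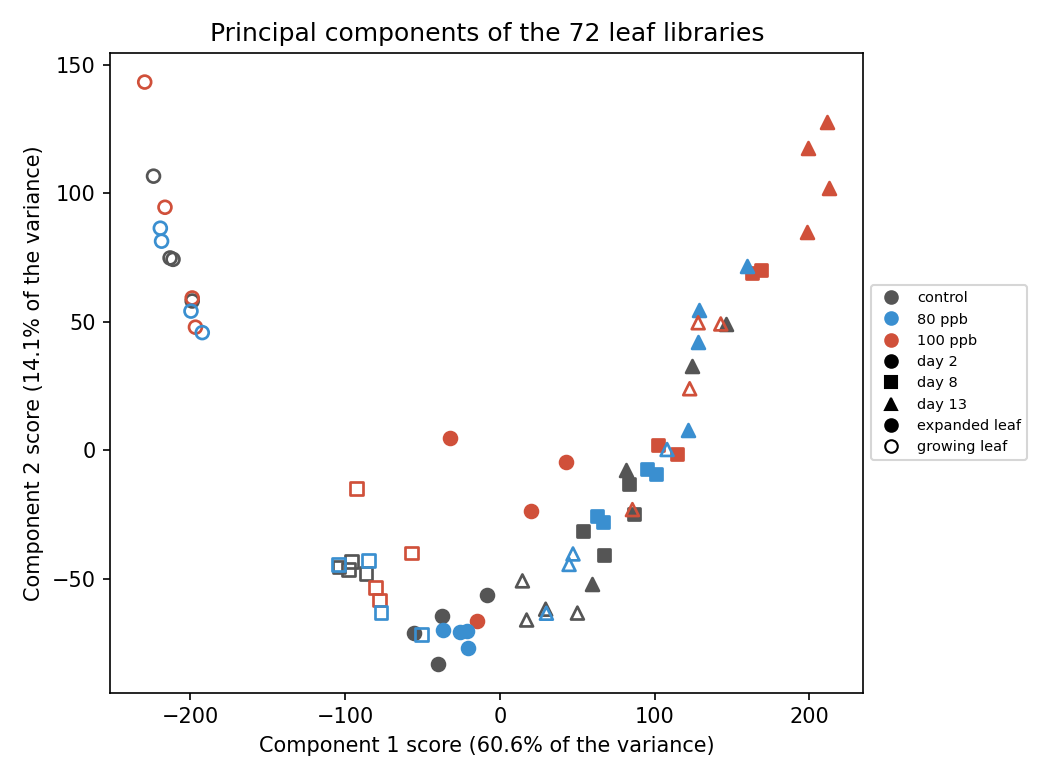
Scores of the 72 libraries on the first (60.6% of the variance) and second (14.1%) principal components of the log2 normalised read counts; each point is 1 library, and colour and shape give leaf position, day and treatment. Control growing leaves run from a mean of −212 on day 2 to 27.9 on day 13 on the first component, and leaves at 100 ppb lie above their controls on day 13 (205 against 103 in expanded and 120 against 27.9 in growing leaves).

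The title of the series asks how genes that respond to ozone are regulated as leaves develop, so growing and expanded leaves in filtered air were compared first. Potri.019G024600 had 45750 ± 6900 normalised reads in growing leaves on day 2 and 0.256 ± 0.512 in expanded leaves (log2 change 15.21 ± 0.83, adjusted p = 6.32e-23). Potri.002G252200 had 11690 ± 5280 against 0.256 ± 0.512 (13.15 ± 0.62, adjusted p = 1.64e-25). Each rests on 1 read in the expanded leaves, which gives ratios of 177000 (95% counting interval 31800 to 6990000) and 45400 (8150 to 1790000). Potri.017G144061 had no read in the 4 growing leaf libraries against 1333 ± 186 in expanded leaves, at least 1640-fold lower when 3 reads over the group are taken as the floor (adjusted p = 1.97e-29). Potri.014G149700 fell from 12720 ± 952 in expanded to 15.7 ± 11.4 in growing leaves (−9.84 ± 0.55, adjusted p = 1.73e-22). Intervals and floors cover counting error only.

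On day 2, 17488 genes (63% of those tested) differed between the leaf positions, 9023 higher and 8465 lower in growing leaves, and 8217 of them by at least 2-fold. On day 8 the count was 15106 (7540 higher, 7566 lower) and on day 13 it was 6938 (4156 higher, 2782 lower). Over the same time the control growing leaves themselves changed in 14428 genes from day 2 to day 8 and in 19466 from day 2 to day 13, contrasts added after the data were seen. Without replicate 2 of the expanded controls the day 13 count was 4425, and with the spread of the compared libraries alone 2231, but scaled to equal totals it rose to 11800, of which 5443 were shared with the 6938. The share of higher genes on day 8 was from 27.7% to 56.3% over the alternatives (libraries left out aside), so no majority direction held. With every library scaled to the same total, the median of all genes shifted to −0.32 on day 8 and −0.26 on day 13, and the share of changed genes that were higher went from 49.9% to 27.7% and from 59.9% to 22.6%.

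In expanded leaves, genes passed the test at 100 ppb ozone on day 2 already. Potri.017G045100 rose from 2.37 ± 2.85 to 147 ± 141 (4.98 ± 0.99, adjusted p = 0.00116) and Potri.006G042200 from 17.1 ± 27.6 to 434 ± 439 (4.72 ± 1.10, adjusted p = 0.00569). Potri.019G057500 fell from 6879 ± 2000 to 626 ± 372 (−3.60 ± 0.58, adjusted p = 7.87e-05) and Potri.001G254100 from 3832 ± 1000 to 396 ± 197 (−3.43 ± 0.64, adjusted p = 5e-04). Control replicate 2 held 58.4 of Potri.006G042200 and the other controls 0.935 to 7.17, and 100 ppb replicate 4, at 14.4, lay below the control mean of the counts though above that of their log2 values. In all, 2316 genes changed, 1317 higher and 999 lower, and 869 by at least 2-fold. The count was 1148, 1436 and 849 without control replicates 1, 3 and 4, and 456, 1065 and 4243 without 100 ppb replicates 1, 2 and 4. The call for Potri.006G042200 was lost without 100 ppb replicate 1 (adjusted p = 0.0504) and with the spread estimated from the compared libraries alone (adjusted p = 0.119; range over its alternatives 0.000244 to 0.119), a fit in which 40 genes changed. Of the changed genes 56.9% were higher as deposited, 81.1% when scaled to equal totals, 47.3% with TMM scaling and 42.5% with the spread of the compared libraries alone, so no majority direction held.

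On day 8, Potri.015G023900 rose from 31.2 ± 11.9 to 1445 ± 752 (5.44 ± 0.97, adjusted p = 0.000157) and Potri.015G024000 from 65.1 ± 37.9 to 2618 ± 1490 (5.35 ± 0.97, adjusted p = 0.000185). Their identifiers are close in number, and whether they are separate examples was not assessed. Potri.019G031200 fell from 598 ± 302 to 5.45 ± 4.41 (−6.73 ± 0.96, adjusted p = 6.37e-06) and Potri.013G080300 from 2776 ± 1140 to 80.3 ± 45 (−5.27 ± 0.96, adjusted p = 0.000193). A total of 5468 genes changed, 3104 higher and 2364 lower, with 2146 at 2-fold or more. The count was 3325 without control replicate 2, 2993 without 100 ppb replicate 1 and 2138 without 100 ppb replicate 4, and 2169 with the spread of the compared libraries alone.

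By day 13, Potri.001G374600 had risen from 1.2 ± 1.0 to 689 ± 210 (8.36 ± 0.80, adjusted p = 3.12e-12) and Potri.002G025350 from 7.17 ± 6.48 to 1942 ± 1640 (7.91 ± 0.81, adjusted p = 2.1e-11) in expanded leaves at 100 ppb. Potri.019G031200 fell from 242 ± 323 to 0.581 ± 0.778 (adjusted p = 2.58e-07). This rests on 3 reads in the 100 ppb group, and the control level was 398 times that at 100 ppb (95% counting interval 136 to 1930). Potri.004G214833 fell from 210 ± 132 to 7.14 ± 14.3 (−6.20 ± 1.26, adjusted p = 6.29e-05). In the 100 ppb group replicate 1 stood apart for Potri.001G374600 (378, others 746 to 822) and Potri.004G214833 (28.6, others 0), and control replicate 3 for Potri.019G031200 (722, others 31.6 to 130). Altogether 11413 genes (41.1%) changed, 6143 higher and 5270 lower, and 4981 of them by at least 2-fold. With the spread of the compared libraries alone the count was 6337. Scaled to equal totals, 44.3% of the changed genes were higher, against 53.8%, so the majority turned to lower, as it did under none of the other 11 alternatives (libraries left out aside).

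In growing leaves, 100 ppb ozone changed few genes on days 2 and 8. On day 2, Potri.006G155500 rose from 519 ± 39.1 to 1141 ± 242 (1.11 ± 0.23, adjusted p = 0.0384) and Potri.005G096800 from 282 ± 33 to 432 ± 46.9 (0.61 ± 0.13, adjusted p = 0.0384). Potri.008G135200 fell from 1082 ± 326 to 368 ± 236 (−1.72 ± 0.35, adjusted p = 0.0302) and Potri.009G041100 from 9147 ± 1680 to 4301 ± 1510 (−1.13 ± 0.23, adjusted p = 0.0302). These were among 15 changed genes, 7 higher and 8 lower; 11 of the 35 splits of these 8 libraries gave at least as many, so chance was not excluded. EdgeR called 3 genes and DESeq2 28, and the majority direction turned under 4 of 11 alternatives. The 4 calls were lost in 8, 11, 8 and 8 of 20 alternatives: by edgeR the adjusted p-values were 0.076, 0.076, 0.111 and 0.076, and over all alternatives they reached from 0.00943 to 0.498, 0.00842 to 0.977, 0.00254 to 0.977 and 0.00307 to 0.977. Without control replicates 1, 2, 3 and 4 the count was 5, 216, 4 and 8, without 100 ppb replicates 1 and 2 it was 482 and 9, and with the spread of the compared libraries alone no gene changed. All 4 calls were lost without control replicate 1, 3 or 4 or 100 ppb replicate 2, the first 2 without 100 ppb replicate 3, and the last 3 without 100 ppb replicate 4.

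On day 8, Potri.008G212500 rose from 24.5 ± 13.8 to 151 ± 52.1 (2.67 ± 0.47, adjusted p = 0.00622) and Potri.004G182000 from 224 ± 54.1 to 1290 ± 934 (2.31 ± 0.50, adjusted p = 0.0464). Potri.015G013100 fell from 104 ± 17.2 to 37.7 ± 15.6 (−1.51 ± 0.29, adjusted p = 0.0148) and Potri.016G025600 from 2301 ± 252 to 1202 ± 101 (−0.93 ± 0.18, adjusted p = 0.0148). Changed genes numbered 11, 8 higher and 3 lower, against 7 by edgeR, 58 by DESeq2 and 49 with the spread of the compared libraries alone. Of these 49, 30.6% were higher, as were 29.4% with a pseudocount of 8, against 72.7%, so the majority turned. The count was 6 and 3 without control replicates 1 and 3, and 7, 7 and 41 without 100 ppb replicates 1, 2 and 3. The call for Potri.004G182000 was lost without any one of the 4 control libraries or 100 ppb replicate 1, 2 or 4 (adjusted p = 0.0614 to 0.283), that for Potri.008G212500 without control replicate 1 (0.0503), that for Potri.015G013100 without control replicate 3 or 100 ppb replicate 2 or 3 (0.0555 to 0.106), and that for Potri.016G025600 without control replicate 3 or 100 ppb replicate 4 (0.106 and 0.0649).

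On day 13 growing leaves at 100 ppb changed in 7773 genes (28%), 4727 higher and 3046 lower, with 3242 at 2-fold or more. Potri.015G023900 rose from 17.9 ± 4.19 to 5640 ± 7450 (7.41 ± 0.97, adjusted p = 2.11e-07) and Potri.002G155300 from 3.28 ± 2.78 to 1143 ± 922 (6.96 ± 1.37, adjusted p = 9.27e-05). Replicate 4 at 100 ppb held 16760 of Potri.015G023900 and the others 1090 to 2727. Potri.001G254100 fell from 487 ± 387 to 40.8 ± 40.6 (−3.94 ± 0.64, adjusted p = 4.8e-06) and Potri.011G140400 from 230 ± 323 to 19.2 ± 20.2 (−3.52 ± 1.20, adjusted p = 0.0224). The call for Potri.011G140400 was lost without control replicate 2, which held 713 against 41.6 to 107 in the other controls (adjusted p = 0.125), without 100 ppb replicate 3 (0.184) and with the spread of the compared libraries alone (0.0608), within a range of 0.00598 to 0.184. Scaled to equal totals, the median of all genes shifted to 0.13 and 78.8% of the changed genes were higher, against 60.8%.

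**Figure D2:**
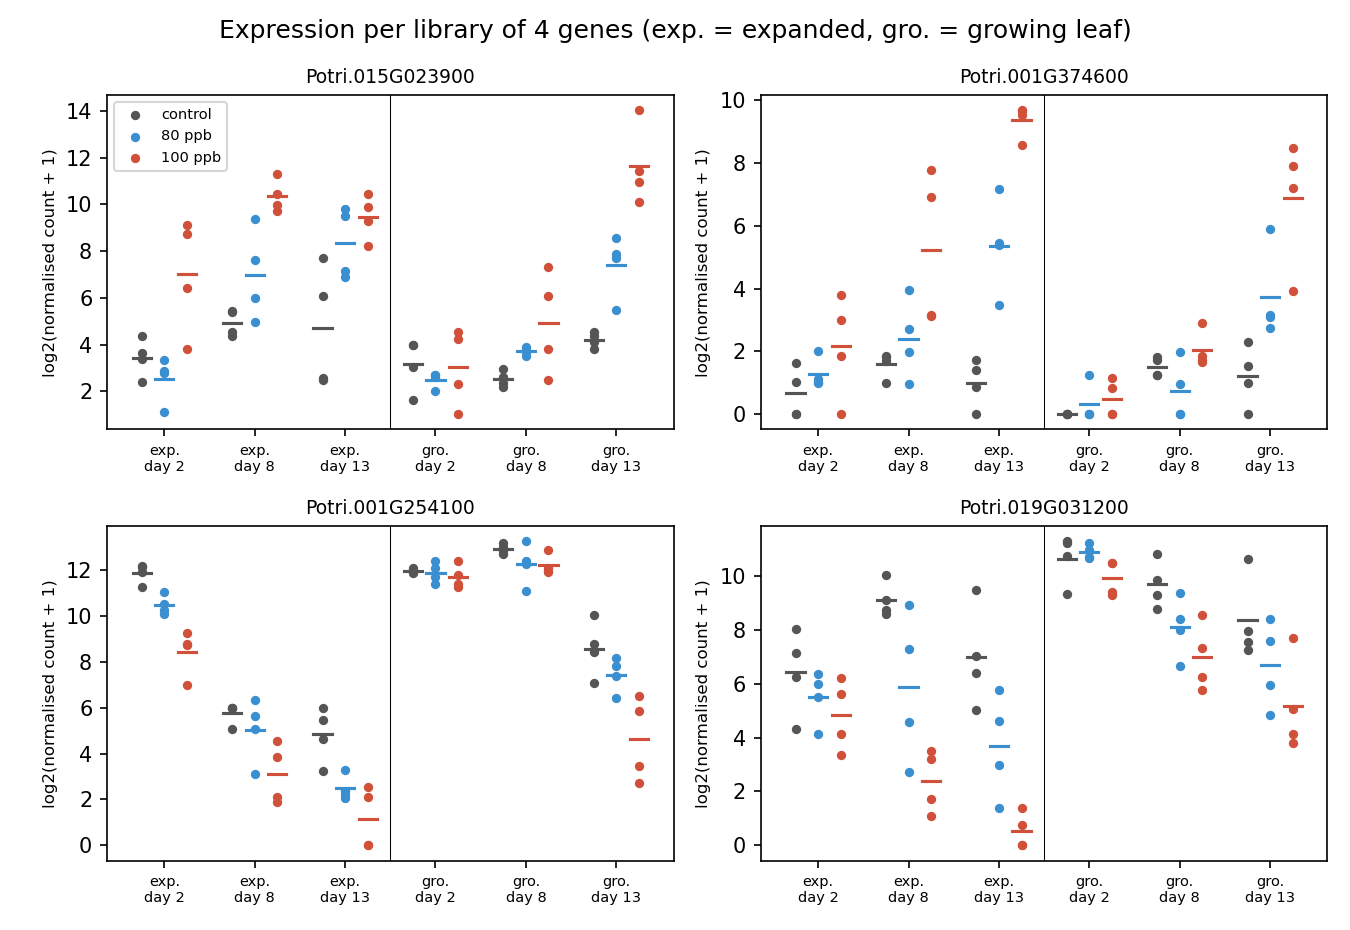
Log2(normalised read count + 1) of 4 genes by leaf position, day and treatment; points are libraries and bars mark the means of the log2 values of 4 libraries. At 100 ppb on day 13 in growing leaves Potri.015G023900 lay at 5640 ± 7450 normalised reads against 17.9 ± 4.19 in controls (SD, n = 4), and Potri.001G254100 at 40.8 ± 40.6 against 487 ± 387.

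At 80 ppb few genes passed the test on days 2 and 8, and in growing leaves on day 13 too. The genes named here for days 2 and 8 of expanded leaves and day 13 of growing leaves were chosen after their values were seen. In expanded leaves on day 2, Potri.006G155500 rose from 1924 ± 338 to 5345 ± 1410 (1.45 ± 0.23, adjusted p = 0.00188), while Potri.005G259300 fell from 87.5 ± 34.5 to 27.5 ± 5.42 (−1.58 ± 0.26, adjusted p = 0.00188) and Potri.007G120002 from 38.4 ± 7.05 to 14.2 ± 4.34 (−1.39 ± 0.25, adjusted p = 0.00887). These were the 3 changed genes. On day 8, Potri.014G150200 rose from 786 ± 43.9 to 4831 ± 2320 (2.48 ± 0.33, adjusted p = 1.1e-05), Potri.001G123300 rose from 1.43 ± 1.72 to 18.9 ± 7.58 (3.27 ± 0.52, adjusted p = 0.000452) and Potri.012G047200 fell from 799 ± 144 to 371 ± 129 (−1.15 ± 0.22, adjusted p = 0.0135), among 5 changed genes (4 higher, 1 lower). On day 13, 485 genes changed in expanded leaves, 237 higher and 248 lower, and 263 by at least 2-fold; 4 of the 35 splits of these 8 libraries gave at least as many, so chance was not excluded.

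In growing leaves at 80 ppb, Potri.014G150200 rose on day 13 from 793 ± 75.8 to 4467 ± 1280 (2.45 ± 0.33, adjusted p = 1.55e-05) and Potri.001G123300 from 3.21 ± 1.35 to 28.2 ± 7.27 (2.82 ± 0.52, adjusted p = 0.00872), among 4 genes that were all higher. Limma called 0 genes on days 2 and 8, where 584 and 1240 genes had an unadjusted p under 0.05. Both counts are below a share of 0.05 of the 27780 tested genes, the number expected without any response. EdgeR also called 0 on both days, and DESeq2 called 0 and 1.

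The counts at 80 ppb moved with single libraries. On day 13 in expanded leaves the count was 180 and 817 without control replicates 2 and 4, and 142, 40, 140 and 1612 without 80 ppb replicates 1, 2, 3 and 4; it was 766 by edgeR, 1120 by DESeq2 and 0 with the spread of the compared libraries alone, and the share of higher genes, 48.9%, was from 46.4% to 69.1% over the alternatives, so no majority direction held. With the spread of the compared libraries alone 16 genes were called in expanded leaves on day 2, 1 of them among the 3, no gene there on day 8 and 1 gene in growing leaves on day 13; DESeq2 called 8, 9 and 36. It was 1 without control replicate 1 on day 2 and 10 without 80 ppb replicate 2 on day 8 in expanded leaves, and 2 without 80 ppb replicate 2 on day 13 in growing leaves. With equal totals 50% of the changed genes of day 2 in expanded leaves were higher, against 33.3%. In growing leaves the day 2 count was 2 and 3 without control replicates 2 and 4, and 1 without 80 ppb replicate 1 or 3. The day 8 count there was 2, 1 and 3 without control replicates 2, 3 and 4, and 8 without 80 ppb replicate 2.

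**Figure D3:**
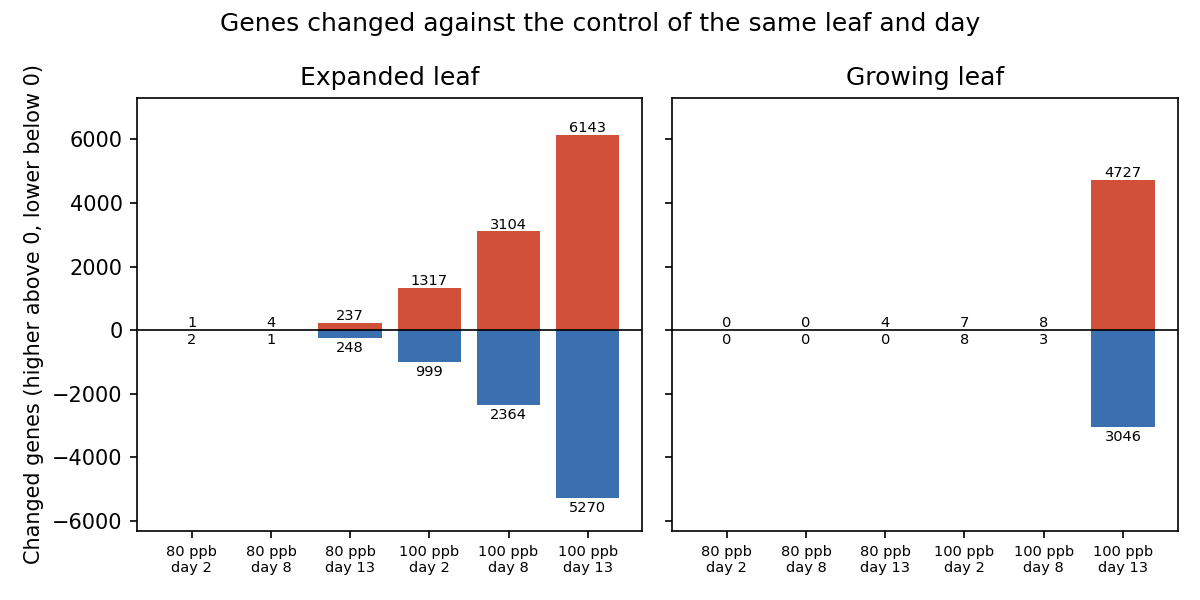
Number of genes changed against the control of the same leaf position and day at an adjusted p of 0.05 (limma), with higher genes above 0 and lower genes below 0, for each ozone level, day and leaf position. At 100 ppb the counts in expanded leaves were 2316, 5468 and 11413 on days 2, 8 and 13, and in growing leaves 15, 11 and 7773.

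Whether 100 ppb changed expression more than 80 ppb was tested on the mean of the 3 days. In expanded leaves 9763 genes differed, 5527 higher and 4236 lower at 100 ppb. In growing leaves 16 differed, 14 higher and 2 lower, and 6 of 100 splits gave at least as many, so chance was not excluded there. Tested day by day, a choice made after the data were seen, the counts in expanded leaves were 1901, 2264 and 8117 on days 2, 8 and 13. In growing leaves they were 0, 0 and 4150 by limma, with 2267 and 818 genes at an unadjusted p under 0.05 on days 2 and 8, and no other tool was run on these daily contrasts. Without any difference a share of 0.05 of the 27780 tested genes would be expected there, fewer than 2267 but more than 818. The count of 16 in growing leaves moved with most libraries. Of day 2, it was 286 without 80 ppb replicate 1, 961 without 100 ppb replicate 1 and 0 without 80 ppb replicate 2 or 3 or 100 ppb replicate 2 or 4. Of day 8, it was 3 and 9 without 80 ppb replicates 1 and 2, and 1, 0 and 4 without 100 ppb replicates 1, 3 and 4. Of day 13, it was 1152 without 80 ppb replicate 3, 2384 without 100 ppb replicate 1 and 0 without 80 ppb replicate 2 or 4 or 100 ppb replicate 2, 3 or 4. It was 1056 by DESeq2 and 847 with equal totals. By edgeR, with a pseudocount of 8 and with the spread of the compared libraries alone it was 0.

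The difference of the ozone response between the leaf positions was tested directly, first on the mean of both ozone levels. On day 13, Potri.017G010300 (2.55 ± 0.55, adjusted p = 0.0217) and Potri.010G067100 (2.22 ± 0.43, adjusted p = 0.00936) responded more positively in growing than in expanded leaves. At 100 ppb both fell in both positions, but less in growing leaves. Potri.017G010300 went from 81.9 ± 43 to 2.01 ± 2.06 in expanded and from 200 ± 93.7 to 87.3 ± 57.2 in growing leaves. Potri.010G067100 went from 370 ± 185 to 19.75 ± 14 in expanded and from 1274 ± 182 to 861 ± 220 in growing leaves. Potri.009G143500 (−3.49 ± 0.72, adjusted p = 0.0144) and Potri.007G002100 (−2.84 ± 0.61, adjusted p = 0.0198) responded more negatively. At 100 ppb both rose in expanded leaves and moved little in growing leaves. Potri.009G143500 went from 17.5 ± 20.4 to 385.5 ± 346 in expanded and from 15.6 ± 5.22 to 10.55 ± 4.51 in growing leaves. Potri.007G002100 went from 29.8 ± 26.8 to 334 ± 132 in expanded and from 50.5 ± 16.4 to 58.7 ± 19.1 in growing leaves. These 4 genes were among 74, 46 with a more positive and 28 with a more negative response in growing leaves. With the spread of the compared libraries alone all 4 calls were lost (adjusted p = 0.349, 0.258, 0.303 and 0.258, the highest over their alternatives, whose lowest were 0.000157, 0.000132, 0.00125 and 0.00154) and no gene passed. By edgeR the count was 166, by DESeq2 333, and with the replicate number as a block within day and treatment 161. The call for Potri.017G010300 was also lost without expanded control replicate 3 or growing control replicate 1 or 4, and with a pseudocount of 8 (adjusted p = 0.0608 to 0.0912). The call for Potri.007G002100 was also lost without expanded control replicate 1 or 3 or growing control replicate 2 (adjusted p = 0.0519 to 0.0792). The count of 74 was 160, 142 and 32 without expanded control replicates 1, 2 and 3, 34 and 133 without expanded 80 ppb replicates 2 and 4, 183, 135 and 28 without expanded 100 ppb replicates 1, 2 and 4, and 19 without growing control replicate 4. With equal totals the median of all genes shifted to 0.11 and 83.8% of the responses called were more positive, against 62.2%; TMM scaling gave 54.2%, and a pseudocount of 8 turned the majority (43.7%).

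On day 8, Potri.011G129400 (−2.25 ± 0.42, adjusted p = 0.0372) and Potri.014G150200 (−2.10 ± 0.40, adjusted p = 0.0372), named after their values were seen, were the 2 genes that differed. The count was 1 without expanded control replicate 4, 5 without expanded 80 ppb replicate 2, 4 without growing control replicate 4 or growing 100 ppb replicate 4, and 0 without any other library, except that it was 2 without expanded 80 ppb replicate 1, expanded 100 ppb replicate 3, growing 80 ppb replicate 4 or growing 100 ppb replicate 1. On day 2 limma called 0 genes (1506 at an unadjusted p under 0.05), edgeR 1 and DESeq2 3. The 1506 lie close to a share of 0.05 of the 27780 tested genes, the number expected without any difference. The day 2 count was 1 without expanded control replicate 2, expanded 80 ppb replicate 2 or growing control replicate 2 or 4, and 2 without expanded control replicate 3, expanded 80 ppb replicate 1 or expanded 100 ppb replicate 2 or 4.

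At 100 ppb alone, a contrast added after the data were seen, the response differed between the leaf positions in 109 genes on day 2 (52 more positive and 57 more negative in growing leaves), 19 on day 8 (7 and 12) and 976 on day 13 (536 and 440). Every one of the 16 libraries moved the day 2 count, which was 30, 185, 55 and 12 without expanded control replicates 1 to 4, 19, 13, 52 and 1107 without expanded 100 ppb replicates 1 to 4, 16, 297, 71 and 29 without growing control replicates 1 to 4, and 907, 213, 25 and 31 without growing 100 ppb replicates 1 to 4. The day 8 count was 3, 0, 0 and 17 without expanded control replicates 1 to 4, 6, 298, 108 and 0 without expanded 100 ppb replicates 1 to 4, 0, 1, 4 and 0 without growing control replicates 1 to 4, and 6, 1, 0 and 11 without growing 100 ppb replicates 1 to 4. The day 13 count was 401 without expanded 100 ppb replicate 4 and 620 without growing control replicate 4. With the spread of the compared libraries alone the counts were 0, 96 and 26 on days 2, 8 and 13. DESeq2 gave 696, 235 and 1517, and edgeR gave 252 on day 2. With the replicate number as a block within day and treatment the counts were 576 and 99 on days 2 and 8, and whether the numbers pair the leaf positions is not settled. With equal totals the median shifted to 0.23 on day 13, and the share of more positive responses went from 54.9% to 90.1% on day 13 and from 47.7% to 29% on day 2, where TMM scaling gave 64%. On day 13 a pseudocount of 8 turned the majority (46.1%) and TMM scaling gave 50.6%, and on day 2 the majority turned under 5 of 12 alternatives.

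How the response to both ozone levels changed from day 2 to day 13 was tested within each leaf position. In growing leaves 431 genes differed, 385 with a more positive and 46 with a more negative response on day 13. In expanded leaves 806 differed, 412 and 394. The expanded leaf count was 516, 479 and 499 without day 2 control replicates 2, 3 and 4, 468, 1252 and 392 without day 13 control replicates 1, 2 and 3, and 448 without day 13 80 ppb replicate 2. It was 394 with the spread of the compared libraries alone and 1359 by DESeq2, which gave 1018 in growing leaves. Of the expanded leaf responses 51.1% were more positive, but from 33.9% (equal totals) to 62.9% over the alternatives, so no majority direction held. The growing leaf count was 146, 123 and 106 without day 2 control replicates 1, 3 and 4, 29, 132, 198 and 221 without day 13 control replicates 1 to 4, 286, 78 and 739 without day 13 80 ppb replicates 1, 3 and 4, and 1795, 117, 109 and 229 without day 13 100 ppb replicates 1 to 4.

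On day 13 at 100 ppb, 3572 genes were higher in both positions, where independent lists would share 1045, and 1935 were lower in both (577.8). Another 23 were higher in expanded and lower in growing leaves, and 20 the reverse. Across genes, which are not independent replicates, Spearman's rho between the changes in the 2 positions was 0.083 on day 2, 0.328 on day 8 and 0.714 on day 13, with jackknife standard errors over libraries of 0.16, 0.11 and 0.075. The changes in expanded leaves on day 8 had a rho of 0.749 with those in growing leaves on day 13, and the calls shared were 2429 higher and 1243 lower (528.2 and 259.2 if independent), with 0 in opposite directions. At 80 ppb rho between the positions was 0.165, 0.0598 and 0.358 on days 2, 8 and 13. These comparisons share no library.

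**Figure D4:**
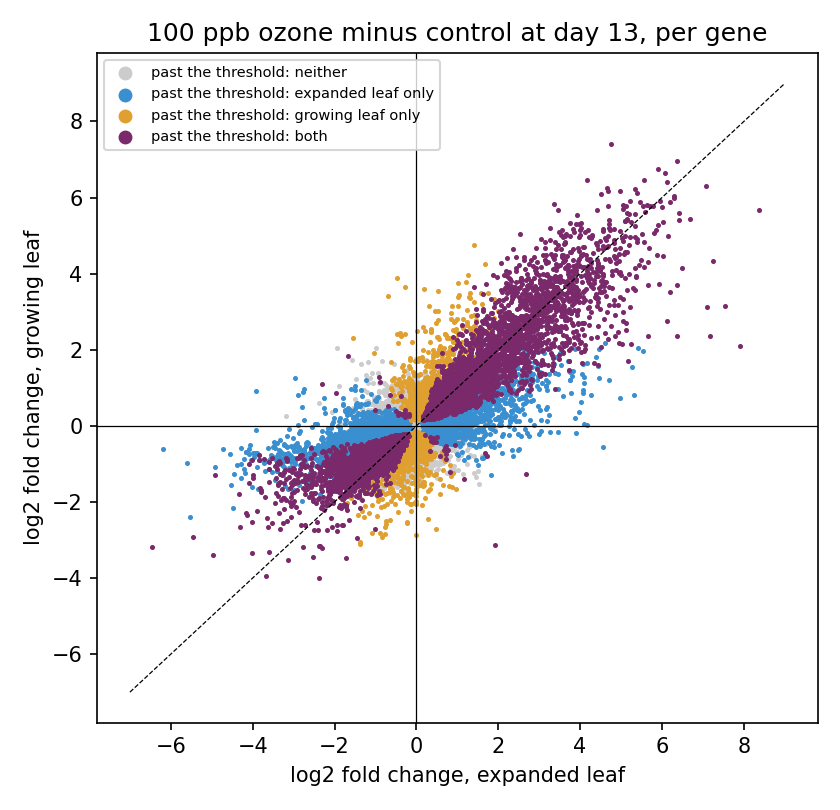
Log2 change at 100 ppb ozone against control on day 13 in expanded (horizontal) and growing leaves (vertical); each point is 1 tested gene, colour marks where it passed the test and the dashed line marks equal change. Spearman's rho over the 27780 genes was 0.714, with 3572 genes higher and 1935 lower in both positions.

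Within expanded leaves at 100 ppb, 602 genes were higher and 239 lower on all 3 days, and of these 558 and 197 were also higher and lower in growing leaves on day 13. Independent lists would share 32.5 and 16.1 over the 3 days, each of which has its own control libraries. Of the 13260 genes that changed on at least 1 day, 54 changed in opposite directions between days.

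The changes at 80 and 100 ppb were compared with the control libraries split between them, so that no library was shared. In expanded leaves rho was 0.0729, 0.299 and 0.371 on days 2, 8 and 13, and in growing leaves −0.0568, 0.235 and 0.406. The jackknife standard errors over the 8 treated libraries were 0.12, 0.17 and 0.1 in expanded and 0.17, 0.14 and 0.18 in growing leaves, and without 80 ppb replicate 3 the last rho fell to 0.218. Against all 4 shared controls rho was 0.279, 0.531 and 0.604 in expanded and 0.272, 0.555 and 0.66 in growing leaves, where unchanged groups simulated against shared controls gave 0.452 to 0.453. The covariance with shared controls on day 13 was 0.427 in expanded and 0.29 in growing leaves, beside 0.0547 and 0.0534 in the simulation. The simulation took a single spread per gene over all groups. Expanded controls of day 13 were the most spread group (median SD 0.308), so the simulated value may lie too low there. On day 2 it was 0.0624 and 0.0333, beside 0.0536 and 0.0537, and on day 8 it was 0.138 and 0.0715, beside 0.0539 and 0.0535.

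To relate ozone to leaf position, the mean response to both levels on day 13 was set against the growing minus expanded difference in controls of another day. With day 2 controls rho was −0.111 in expanded leaves and −0.115 in growing leaves, with jackknife standard errors of 0.092 and 0.11, so neither lay beyond 2 standard errors. With day 8 controls rho was −0.28 (0.18) and −0.372 (0.13). In growing leaves 1162 genes higher with ozone were lower in growing than in expanded controls on day 8, where independent lists would share 675.4, and 140 were higher in both (673.1). Against the controls of day 13 itself, which enter both sides, rho was −0.356 in expanded and −0.603 in growing leaves, where simulated unchanged groups gave 0.527 and −0.527.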

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

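Chosen only after their results were seen were the tests of exchanged labels, of the shared replicate number and of depth in growing leaves, those of shared controls, that of genes outside the expanded set, that of a bias with expression level on day 8 controls, and the contrasts at 100 ppb alone. The number of splits drawn was also raised, from 50 to 100, after the first counts had been seen.

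In 9 of 116 checks of 4 libraries, 1 library lay apart by a gap of more than 0.829 of the range. For normally distributed values about 5.8 would be flagged at 1 in 20. Read counts are skewed, and a single read among zeros is always flagged, so 5.8 is not a fair expectation here. Replicate 3 of the growing controls of day 2 had 33.8 M reads (others 38.6 M to 39 M). Potri.006G042200 had 58.4 normalised reads in expanded control replicate 2 of day 2 (others 0.935 to 7.17). In expanded leaves at 100 ppb on day 13, replicate 1 had 378 for Potri.001G374600 (others 746 to 822) and 28.6 for Potri.004G214833 (others 0). In expanded control replicate 3 of day 13 Potri.019G031200 had 722 (others 31.6 to 130). Potri.015G023900 had 16760 in growing leaf replicate 4 at 100 ppb on day 13 (others 1090 to 2727), and Potri.011G140400 had 713 in growing control replicate 2 of day 13 (others 41.6 to 107). Potri.019G024600 and Potri.002G252200 each had 1.02 in expanded control replicate 3 of day 2, which is 1 read (others 0).

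The response to ozone differed between the leaf positions, by a direct test of the difference, in 2 genes on day 8 and 74 on day 13 for the mean of both levels, and in 109, 19 and 976 genes on days 2, 8 and 13 at 100 ppb alone. The log2 differences of the genes named were 2.55 for Potri.017G010300, 2.22 for Potri.010G067100, −3.49 for Potri.009G143500 and −2.84 for Potri.007G002100. From day 2 to day 13 the response differed in 806 genes in expanded and 431 in growing leaves.

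Splits that exchanged the labels within pairs of groups were drawn for these differences, 100 with the real one included. As many genes as the real split were reached by 100 on day 2 (real 0, highest other 2), 2 on day 8 (real 2, highest other 2) and 3 on day 13 (real 74, highest other 601) for the difference between leaf positions, and by 1 (real 806, highest other 478) and 3 (real 431, highest other 1686) for the change over time in expanded and growing leaves. The share was under 0.05 except on day 2, where a real count of 0 fixes it in advance, and it was not adjusted over the contrasts. On day 8 chance is not excluded, since the real count of 2 was tied by another split. That count was also 0 with equal totals and without most single libraries. With the 50 splits drawn first the numbers of splits reaching the real count were 50, 1, 3, 1 and 1, with highest other counts of 2, 0, 1086, 120 and 2. The day 13 share between leaf positions was then 0.06, on the other side of 0.05 from the 0.03 of 100 splits, so its place under 0.05 rests on the number drawn. Splits that call 601 or 1686 genes, several times the real count, point to a structure of the samples that the groups do not describe.

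Libraries of one group at 100 ppb responded unequally: the score over genes that rose on day 13 ranged from 0.114 to 1.2 on day 2 and from 0.394 to 1.93 on day 8 in expanded leaves, and from 0.629 to 2.29 on day 13 in growing leaves, but this is no trait of 100 ppb alone, since expanded controls of day 13 (scored on genes of day 8) ranged from −1.02 to 0.741 and expanded leaves at 100 ppb that day from 2.41 to 2.87. Unequal depth is argued against, since thinning every library to the shallowest kept at least 0.951 of the range. Exchanged labels are argued against in expanded leaves as the cause of the range, since the 4 highest scores of all 12 libraries still spanned at least 0.911 of it, although control replicate 2 (0.21) and 80 ppb replicate 4 (0.121) lay above 100 ppb replicate 4 (0.114) on day 2 and 80 ppb replicate 3 (0.429) above 100 ppb replicate 2 (0.394) on day 8. Whether those labels were exchanged is another question, which the range cannot decide, because such close scores hardly alter it. In growing leaves on day 13 an exchange cannot be told apart from an unequal response, since 80 ppb replicate 3 lay above 100 ppb replicate 1 in score (1.12 against 0.629), on the first principal component (108 against 85.7) and in Potri.002G155300 (334 against 9.67 normalised reads), but below it in Potri.015G023900 (378 against 1090), while the 4 highest scores still spanned 0.703 of the range; a wrong label without a partner stays open throughout. A factor shared by libraries of one replicate number may contribute, as same-numbered expanded and growing leaves at 100 ppb deviated together (mean correlation 0.147 over 12 pairs, exact one-sided permutation p = 0.00195), but what that number marks is not in the labels, and a difference in ozone uptake between trees was not tested.

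Growing leaves at 100 ppb had few changed genes on days 2 and 8, 15 and 11 against 2316 and 5468 in expanded leaves. A response of equal size hidden by a wider spread is argued against: the score averaged 0.0391 ± 0.0167 in growing and 0.731 ± 0.47 in expanded leaves on day 2, and 0.154 ± 0.17 and 1.16 ± 0.793 on day 8 (SD, n = 4; exact two-sided permutation p = 0.0286 on each day, the smallest possible; adjusted over 3 days 0.0286). That score uses genes chosen from expanded leaves; with 2365 genes chosen from growing leaves it averaged 0.0475 and 0.9 on day 2 and 0.209 ± 0.229 and 1.29 ± 0.877 on day 8 (growing and expanded, exact permutation p = 0.0286 and 0.0571), and over the 454 of them outside the expanded set the gap was 0.511 (jackknife standard error 0.21) and 0.482 (0.27), so the choice of genes is argued against on day 2, while on day 8 it cannot be told apart from a weaker response, because the gap there lies within 2 standard errors. Depth is argued against, as growing leaf libraries held 0.904 and 0.875 of the reads of expanded ones. A later onset in growing leaves is a candidate explanation that the leaf positions of the design allow, and it stays untested beyond these values. Days of ozone ran together with the change of growing leaves over time, since their controls changed in 19466 genes from day 2 to day 13. The design does not separate them. On day 2 exchanged labels of control replicate 2 and 100 ppb replicate 1, picked because that split called 3821 genes, cannot be told apart from the labels as given. The scores (−0.001 and 0.057) and Potri.006G155500 (541 and 1467 normalised reads, controls 468 to 557, other ozone libraries 898 to 1153) ran with the labels. Leaving out either library gave 216 and 482 genes. On 120 genes chosen without both, control replicate 2 scored 1.43 and 100 ppb replicate 1 scored 0.019. Each other library was scored on a gene set of its own. Other controls reached −0.0647 (on 14 to 18 genes), and other ozone libraries began at −0.627 at 80 ppb and −0.0344 at 100 ppb (on 30 to 791 genes). These scores share no scale, so they do not decide. The rho of the day 2 change with the day 13 response was 0.023 exchanged and 0.0567 as given (jackknife standard errors 0.07 and 0.065).

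Across genes the day 13 ozone response and the growing minus expanded difference tended to run in opposite directions, but in expanded leaves no comparison without a shared library lay beyond 2 standard errors: rho was −0.111 (standard error 0.092) with day 2 controls and −0.28 (0.18) with day 8 controls. In expanded leaves shared control libraries are argued against, because they enter both sides with the same sign and push rho above 0, while the same-day rho was −0.356 with a jackknife standard error of 0.17, a margin only just over 2 standard errors. In growing leaves they push rho below 0, and with no shared library rho was −0.115 (standard error 0.11) with day 2 controls, where shared libraries cannot be told apart from a real relation, and −0.372 (0.13) with day 8 controls, which argues against them. A bias with expression level is argued against with day 8 controls, as rho stayed at or below −0.127 in each of 10 classes of expression level in both positions (in expanded leaves within a relation that is itself uncertain), but with day 2 controls it stays open, as rho reached 0.193. That treated leaves may be further along the path of ageing control leaves stays open too: rho with the change of control growing leaves from day 2 to day 8 was 0.0845 in growing and 0.0945 in expanded leaves.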

How the results depend on the processing

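The contrasts at 100 ppb alone and the tests of same-numbered libraries were chosen after the data were seen, and the other alternatives were planned. Camera with an estimated correlation and fry were not run, because no gene lists could be made. Apart from libraries left out, 224 counts stayed within 1.5 times of those reported and 85 did not; of named gene calls 365 were kept, 25 were lost and none reversed, and with a library left out 277 were kept and 43 lost. For counts that moved, the cause was not tested unless named. Depth limits genes with few reads, whose log2 changes depend on the pseudocount.

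At a 2-fold threshold, which by construction calls fewer genes, the counts were 263 for 80 ppb in expanded leaves on day 13, 869, 2146 and 4981 for 100 ppb in expanded leaves on days 2, 8 and 13, 3242 for 100 ppb in growing leaves on day 13, 8217, 6366 and 2685 between leaf positions in controls, 2012 and 8 between ozone levels in expanded and growing leaves, 533 over time in expanded leaves, and 54 and 532 for the response difference at 100 ppb on days 2 and 13. With a pseudocount of 8 they were 2 for 80 ppb and 1 for 100 ppb in growing leaves on day 2, 17 for 100 ppb there on day 8, 0 between ozone levels there, and 4 (both levels) and 49 (100 ppb) for the day 8 response difference. With a pseudocount of 0.25 they were 7 and 1 for 80 ppb in growing leaves on days 2 and 8, 36 for 100 ppb there on day 2, 26 between ozone levels there and 5 for the day 2 response difference of both levels. Without a filter they were 25 and 7 for 80 ppb and 71 and 18 for 100 ppb in growing leaves on days 2 and 8, and 6 for the day 2 response difference of both levels. A filter at 50 gave 12 for the day 8 response difference at 100 ppb, and TMM scaling gave 186 for that of day 2. With equal totals the counts were 6 for 100 ppb in growing leaves on day 8, 11800 between leaf positions on day 13, 847 between ozone levels in growing leaves, 0 for the day 8 response difference of both levels, and 31, 0 and 1918 for that at 100 ppb on days 2, 8 and 13.

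With the compared libraries alone, which estimate the spread from fewer samples, the counts were 16, 0 and 0 for 80 ppb and 40, 2169 and 6337 for 100 ppb in expanded leaves on days 2, 8 and 13. In growing leaves they were 1 for 80 ppb on day 13, and 0 and 49 for 100 ppb on days 2 and 8. Between leaf positions on day 13 the count was 2231, between ozone levels in growing leaves 0 and over time in expanded leaves 394. For the response difference it was 5, 4 and 0 (both levels) and 0, 96 and 26 (100 ppb) on days 2, 8 and 13. By edgeR the counts were 766 for 80 ppb in expanded leaves on day 13, 3 and 7 for 100 ppb in growing leaves on days 2 and 8, 0 between ozone levels there, 1, 1 and 166 for the response difference of both levels on days 2, 8 and 13, and 252 for that at 100 ppb on day 2. By DESeq2 they were 8, 9 and 1120 for 80 ppb in expanded leaves on days 2, 8 and 13, 1 and 36 for 80 ppb in growing leaves on days 8 and 13, 28 and 58 for 100 ppb there on days 2 and 8, 1056 between ozone levels there, 1359 and 1018 over time in expanded and growing leaves, 3, 7 and 333 for the response difference of both levels, and 696, 235 and 1517 for that at 100 ppb.

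Whether the replicate numbers pair the leaf positions is not settled. Same-numbered libraries of the leaf positions had mean correlations of their deviations of 0.0239 in controls, 0.0744 at 80 ppb and 0.147 at 100 ppb. Exact one-sided permutation p-values were 0.186, 0.0645 and 0.00195. Of 12 pairs each, 1, 4 and 7 lay over 0.1, and 28 of 72 libraries correlated best with their own number (18 by chance). At 100 ppb same-numbered leaves thus deviated together, which the main tests, made without a block, do not take into account. With the number as a replicate block the day 2 response difference of both levels was 1 gene, and no other count moved. With the block within day and treatment the response difference was 3 and 161 genes on days 2 and 13 (both levels), and 576 and 99 on days 2 and 8 (100 ppb).

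With leaf position taken from day 8 controls, rho with ozone was −0.28 in expanded and −0.372 in growing leaves. Pearson's r was 0.815 between leaf positions at 100 ppb on day 13, and 0.517 and 0.608 between ozone levels on day 13 in expanded and growing leaves with split controls. The other 19 correlations moved by less than their spread.

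Leaving out each library in turn gave ranges for 80 ppb of 1 to 4, 4 to 10 and 40 to 1612 in expanded and 0 to 3, 0 to 8 and 2 to 4 in growing leaves on days 2, 8 and 13. For 100 ppb they were 456 to 4243 and 2138 to 6650 in expanded leaves and 4 to 482 and 3 to 41 in growing leaves on days 2 and 8. Between leaf positions on day 13 the range was 4425 to 8901, between ozone levels in growing leaves 0 to 2384, and over time 392 to 1252 in expanded and 29 to 1795 in growing leaves. For the response difference it was 0 to 2, 0 to 5 and 19 to 183 (both levels) and 12 to 1107, 0 to 298 and 401 to 1391 (100 ppb). The correlation between ozone levels in growing leaves on day 13 ranged from 0.218 to 0.474. Counts for 100 ppb on day 13, leaf positions on days 2 and 8 and ozone levels in expanded leaves stayed within 1.5 times.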

Other observations

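The scores, the count of neighbouring genes and the splits below were chosen only after the data had been seen, though before their own results except for the number of splits, which was raised from 50 to 100 after the first counts.

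Genes that rose with ozone tended to stand next to each other in the order of the deposited table, which has no column of positions. In expanded leaves at 100 ppb on day 13, 791 pairs of consecutive tested genes both rose at least 2-fold, where 1000 random orders gave a mean of 288 and at most 336. In growing leaves the pairs were 643 (at most 243). Genes that fell by as much made 277 pairs in expanded leaves (mean 167, at most 203) and 77 in growing leaves (mean 27.4, at most 42). Neighbours that respond together are a candidate explanation; copies of one gene that share reads were not tested and may add to these counts.

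Genes that rose at 100 ppb were also scored at 80 ppb. The mean score was 1.17 ± 0.65 in expanded and 0.507 ± 0.44 in growing leaves on day 13 (SD, n = 4), every treated library above the control mean, with exact two-sided permutation p-values of 0.114 and 0.0571 (0.195 and 0.137 adjusted over 12 tests). On day 8 it was 0.151 ± 0.26 and −0.0049 ± 0.0701, and on day 2 it was 0.0798 ± 0.0432 and −0.0127 ± 0.0359. A weaker form of the 100 ppb response at 80 ppb may hold on day 13, but the lowest of the 6 means, −0.0127, is no larger than its spread, so the earlier days do not decide. At 100 ppb the means were 0.731, 1.16 and 2.64 in expanded and 0.0391, 0.154 and 1.69 in growing leaves. The exact permutation p-values were 0.0571, 0.0286 and 0.0286 in expanded and 0.0857, 0.2 and 0.0286 in growing leaves. Adjusted over 12 tests they were 0.137, 0.114 and 0.114, and 0.171, 0.3 and 0.114. Expanded leaves of day 13 were scored on genes of day 8 and all other groups on genes of day 13. The values 1.17 and 2.64 are therefore not on the scale of the others. With 4 against 4 libraries no exact p can lie under 0.0286, so the adjusted values say nothing about whether a response was present.

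Other splits of the same libraries were counted for the remaining contrasts, 35 for each comparison of 4 with 4. For 100 ppb in expanded leaves only the real split reached the real count on days 2, 8 and 13 (real 2316, 5468 and 11413, highest other 2018, 2113 and 7780). For growing against expanded controls the same held (real 17488, 15106 and 6938, highest other 9072, 5341 and 4813). The real split also ranked first for 100 ppb in growing leaves on days 8 and 13 (real 11 and 7773, highest other 3 and 4927). It did so for 80 ppb in expanded leaves on days 2 and 8 (real 3 and 5, highest other 2 and 0) and in growing leaves on day 13 (real 4, highest other 1). A first rank is the smallest share that 35 splits can give, and it was not adjusted over the contrasts. It argues against chance but does not exclude it. It weighs least for counts of 3 to 11 genes or where another split came near (2018 against 2316). The split with 2018 genes is the one that an exchange of the labels of control replicate 2 and 100 ppb replicate 4 would give. Chance is not excluded for 80 ppb in expanded leaves on day 13, where 4 splits gave at least as many (real 485, highest other 755). The same holds for 100 ppb in growing leaves on day 2, with 11 (real 15, highest other 3821). For 80 ppb in growing leaves on days 2 and 8 the real count was 0 (highest other 244 and 15). All 35 splits then reach it by construction, so the splits decide nothing there. For 100 against 80 ppb over the days, 1 of 100 drawn splits reached the real count in expanded leaves (real 9763, highest other 7340) and 6 in growing leaves (real 16, highest other 311). The share was thus under 0.05 in expanded leaves only. With 50 drawn first the numbers of splits were 1 and 7, with highest other counts of 4115 and 761.

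The split with 3821 genes in growing leaves on day 2 set control replicates 1, 3 and 4 with 100 ppb replicate 1 against the rest, which points to a structure among these samples that the treatment does not describe. It is also the split that an exchange of the labels of control replicate 2 and 100 ppb replicate 1 would give. Its changes had a rho of 0.00243 across genes with those of control growing leaves from day 8 to day 13. Those days come after the day of the split. This rho therefore cannot decide whether the split follows the change of growing leaves over time.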
